A study of Homo sapiens with 12 samples.

How the data were processed

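The series held 12 arrays of total RNA from the human multiple myeloma cell lines ARP1, JJN3 and RPMI-8226, as named in the labels, with 4 treatments per line and 1 array per line and treatment. Cells were seeded at 500000 per ml and treated for 6 h, and biotinylated cRNA was made from 150 ng of total RNA for Affymetrix arrays, per the labels' protocols. The titles of the CPI203 samples give no time, and the 6 h comes from the treatment protocol. The deposited values are log2 probe set levels made by RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. That they are on the log2 scale was read from the values. RMA as published corrects the background, sets all arrays to 1 common distribution of intensities and summarises the probes of a probe set, so changes are relative to the bulk of transcripts. Whether the 12 arrays were normalised together was not given in the sources used here. The array medians lay between 5.304 and 5.375 and no value was missing. The 3' to 5' difference of the GAPDH control probe sets lay between -0.301 and -0.087, and that of actin between 0.226 and 0.448, on the log2 scale, with both differences higher on the RPMI-8226 arrays with LenDex than on those without it.

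Each array had 49386 probe sets. Of these 93 were controls, 45253 had 1 gene symbol in the platform annotation, 1327 had several and 2713 had none. Gene symbols were taken from the annotation table, and 45178 of the single-symbol probe sets had a gene identifier in the RefSeq table used to bring symbols up to date. No gene was named from a probe set with several symbols, and histone, UGT2B and AKR1C probe sets may still pick up near-identical family members. Of the 18239 genes with a single-symbol probe set, each was represented by the probe set with the highest mean over the arrays, and the 15173 at a log2 level of 5 or more on at least 3 arrays were tested.

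The choices of groups, comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were made before the data were examined. Groups came from the treatment label. Each gene was fitted in limma 3.58.1 (R 4.3.3) with cell line and group as terms over all 12 arrays, which left 6 residual degrees of freedom, with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The comparisons were each treatment against control, Combo against CPI203, Combo against LenDex, the interaction, and the average effect of CPI203 and of LenDex over both levels of the other, which set 6 arrays against 6. The line served as a block because same-named samples come from the same line, and deviations of arrays from their group means correlated within a line, from 0.91 to 0.94 in ARP1, 0.82 to 0.88 in JJN3 and 0.83 to 0.89 in RPMI-8226. A difference in response between lines was tested with a moderated F test of the line by drug terms, which assumes that the drugs add on the log2 scale and left 3 residual degrees of freedom.

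The 24 gene lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over lists within a comparison. With an estimated correlation no list passed in any comparison. Fry tests whether the genes of a list move, on balance, one way. The lists were BET-repressed and BET-induced marker genes, MYC targets, histone, P-TEFb and BET protein, cereblon and neosubstrate, plasma cell, interferon-stimulated, glucocorticoid-induced, NF-kB, G1/S, G2/M, cyclin-dependent kinase inhibitor, BCL2 family, unfolded protein response, cholesterol synthesis, immediate early, p53 and ribosomal protein genes, and markers of T cells, monocytes and macrophages, fibroblasts, epithelial cells and B cells. They came from general knowledge and not from these arrays. Named genes were the 10 largest rises and 10 largest falls among called genes that moved the same way in all 3 lines, a panel of 16 genes, the leading members of each list, and, where none passed in a direction, the genes with the smallest p. Genes of the lineage comparison outside these sets (MAF, IGKC and IGHA1) were chosen after their values were seen.

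The fit was tested on simulated data in which 200 of the 15173 genes were changed. For CPI203 against control 31.5% of 1.5-fold, 81.3% of 2-fold and 97% of 3-fold changes were recovered. For the CPI203 average effect the shares were 67%, 95.7% and 99%, for the interaction 0%, 52.8% and 89.3%, and for the line difference in the CPI203 effect 0%, 0% and 48%. The simulated spread was equal between lines, so these shares do not cover effects that differ from line to line. It was taken from the fit of cell line and group, whose residual also holds differences in response between lines. The test of a line difference takes these out of its residual, so its shares may be too low. Alternatives were no level filter, a mean log2 level of 6 or more, all probe sets tested singly, cyclic loess normalisation on top of the deposited values, a variance trend with a robust fit, no line block, leaving out each line, fitting the 2 groups alone, and for panel genes the mean of all probe sets of a gene. Leaving out the JJN3 control array, and averaging the JJN3 and RPMI-8226 arrays of each treatment as 1 replicate, were added after the data were seen. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Probe sets with several or no symbols were left out of the gene-level tests because they name no single gene.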

Results

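Transcript levels were measured on 12 single-colour oligonucleotide arrays of RNA from 3 human multiple myeloma cell lines, which the labels name ARP1, JJN3 and RPMI-8226. Multiple myeloma is a malignancy of plasma cells. Each line gave 1 array for each of 4 groups at 6 h. These were control cells, cells with the BET bromodomain inhibitor CPI203 at 0.01 µM, cells with lenalidomide at 5 µM plus dexamethasone at 0.05 µM (LenDex), and cells with all 3 drugs (Combo). BET proteins bind acetylated histones and help start transcription elongation, lenalidomide directs the cereblon ubiquitin ligase to the lymphoid transcription factors IKZF1 (Ikaros) and IKZF3 (Aiolos), and dexamethasone activates the glucocorticoid receptor. The study asked whether CPI203 improves lenalidomide activity, with Ikaros and MYC named as the pathways of interest. Lenalidomide and dexamethasone were always given together, so these arrays cannot separate the effect of lenalidomide from that of dexamethasone. Levels of IKZF1 and IKZF3 below are those of transcripts and do not measure the proteins. The deposited values were log2 probe set levels, with a median between 5.304 and 5.375 on each array, and 15173 genes were tested. Changes are differences of log2 values between groups, given with the standard error (SE), and each group had n = 3, 1 array per line. With line as a block, the p-values measure how far the changes varied between the 3 lines, pooled over the 4 groups. The number of arrays limits their precision. The JJN3 and RPMI-8226 arrays were alike, so the 3 lines may not be independent replicates. Counts with those arrays averaged are given below. RMA sets arrays that are processed together to 1 common distribution, which would hide a shift of all transcripts together; whether the 12 arrays were processed together was not given.

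Lineage genes separated the arrays labelled ARP1 from those labelled JJN3 and RPMI-8226. MS4A1, which encodes the B cell antigen CD20, was at a log2 level of 4.95 ± 0.36 (SD, n = 4) on the ARP1 arrays, 11.73 ± 0.11 (SD, n = 4) on the JJN3 arrays and 11.71 ± 0.25 (SD, n = 4) on the RPMI-8226 arrays. SDC1, the plasma cell surface proteoglycan CD138, ran the opposite way, at 12.03 ± 0.25, 5.38 ± 0.28 and 5.19 ± 0.18 (SD, n = 4 each), and so did PRDM1, a transcription factor of plasma cell differentiation, at 11.31, 5.43 and 5.38. The median of 7 B cell markers lay between 5.14 and 5.54 on the ARP1 arrays, between 7.26 and 8.78 on the JJN3 arrays and between 7.24 and 9.43 on the RPMI-8226 arrays. The median of 23 plasma cell genes lay between 10.75 and 11.07, between 7.57 and 8.33, and between 7.55 and 8.65. PAX5, another B cell gene, was alike on all arrays, at 7.13, 7.01 and 7.14. MAF, an oncogene that is translocated in the JJN3 and RPMI-8226 lines, was at 11.18 on the ARP1 arrays, 5.74 on the JJN3 arrays and 4.79 on the RPMI-8226 arrays. Across genes, JJN3 and RPMI-8226 arrays correlated with Pearson r from 0.966 to 0.982. The range was 0.900 to 0.909 for ARP1 with JJN3 and 0.891 to 0.903 for ARP1 with RPMI-8226. Within a label it was 0.981 to 0.990 for JJN3 and 0.977 to 0.989 for RPMI-8226, which overlaps the range between these labels. Genes are not independent replicates. The JJN3 control array also differed from the other JJN3 arrays in immunoglobulin genes, with IGKC at 9.32 against 5.35, 5.11 and 5.55 under CPI203, LenDex and Combo, and IGHA1 at 9.84 against 5.72, 5.52 and 6.24. Line names are therefore used below as the labels of the arrays.

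**Figure D1:**
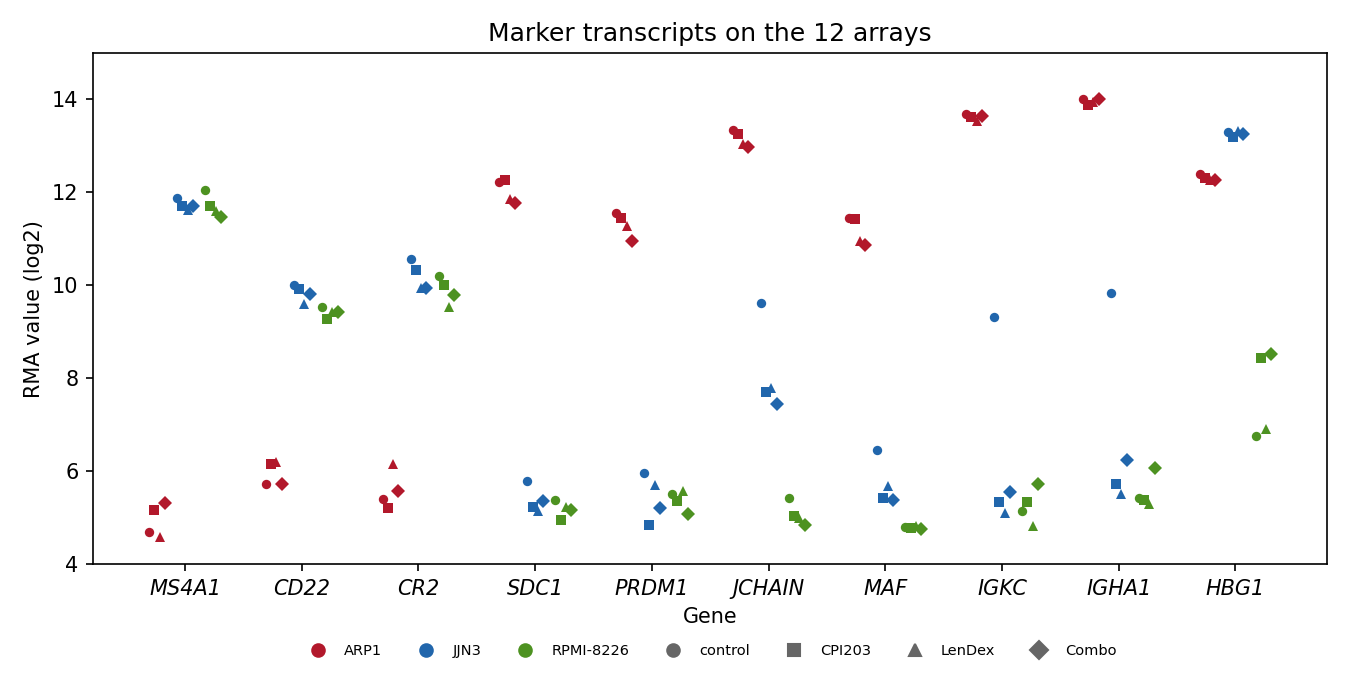
Log2 RMA values (vertical axis) of 10 marker genes (horizontal axis) on each of the 12 arrays; colours give the labelled cell line and symbols the group, 1 point per array. MS4A1, CD22 and CR2 were high on the 8 arrays labelled JJN3 and RPMI-8226, SDC1, PRDM1 and MAF on the 4 ARP1 arrays, and IGKC and IGHA1 stood higher on the JJN3 control array (9.32 and 9.84) than on the other JJN3 arrays.

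CPI203 alone was compared with control to give the effect of the BET inhibitor by itself. The replication-dependent histone gene H3C4 rose by 1.97 ± 0.18 log2 units (SE), a 3.93-fold rise seen in all 3 lines (adjusted p = 0.0128). It was the 1 gene of 15173 that passed, while 2456 genes had an unadjusted p under 0.05. MYC, the oncogenic transcription factor, stood at -0.58 ± 0.15 (adjusted p = 0.115), lower in 3 of 3 lines. IKZF1 stood at -1.18 ± 0.26 (adjusted p = 0.0998) and IKZF3 at -0.70 ± 0.20 (adjusted p = 0.142), each lower in 3 of 3 lines. HEXIM1, an inhibitor of the elongation kinase P-TEFb, was at 1.18 ± 0.31 (adjusted p = 0.124), and the histone gene H2BC21 at 1.95 ± 0.24 (adjusted p = 0.0554), both higher in all 3 lines. Below the threshold, the smallest p-values among genes lower in all 3 lines belonged to SLITRK5 at -0.73 (adjusted p = 0.065), HIVEP3 at -0.92 (adjusted p = 0.065), PTPN6 at -0.93, NFIB at -0.74 and IQSEC1 at -0.86 (adjusted p = 0.0721 for each).

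Among gene groups fixed in advance, 1 of 19 histone genes rose under CPI203 alone, or 14 when adjusted over the list alone, with a list median of 1.05 (camera adjusted p = 2.72e-15, adjusted p = 0.0667 with an estimated correlation). None of the 12 genes known to be induced by BET inhibitors passed over all genes, and 9 rose when adjusted over the list alone (median 1.08, camera adjusted p = 1.05e-08, adjusted p = 0.177 with an estimated correlation). Of 55 MYC target genes none passed over all genes and 20 fell when adjusted over the list alone (median -0.30, camera adjusted p = 3.13e-15, adjusted p = 0.179 with an estimated correlation). The call of H3C4 was lost without JJN3 (0 genes), without RPMI-8226 (0), without the JJN3 control array (0), with the JJN3 and RPMI-8226 arrays averaged (0), with no line block (0) and in a fit of these 6 arrays alone (0). Without ARP1 1015 genes passed, 317 with a variance trend and robust fit (106 higher and 211 lower), 4 after cyclic loess, and 7 probe sets when probe sets were tested singly.

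The average effect of CPI203 compared the 6 arrays with the drug against the 6 without it, over both backgrounds of LenDex. Histone genes were among the largest rises. In each comparison the largest rises and falls were picked among called genes that moved the same way in all 3 lines. For those genes the agreement of lines follows from that choice. H3C4 rose by 1.77 ± 0.13 (3.42-fold, adjusted p = 0.00141), H2AC6 by 1.92 ± 0.23 (adjusted p = 0.00873) and H2BC21 by 1.75 ± 0.17 (adjusted p = 0.00576), in 3 of 3 lines each. SERTAD1, a cell cycle regulator, rose 4.25-fold (2.09 ± 0.41, adjusted p = 0.0223), and the metallothionein gene MT1X 3.37-fold (1.75 ± 0.23, adjusted p = 0.0112). JUND rose by 1.68 ± 0.29, DHRS2 by 1.61 ± 0.29, CSRNP2 by 1.45 ± 0.27, H2AC25 by 1.45 ± 0.34 and H2AC8 by 1.38 ± 0.26. The rises of SERTAD1, MT1X and these 5 genes were called as different between lines and were smallest in ARP1. For SERTAD1 they were 0.51 in ARP1, 2.45 in JJN3 and 3.31 in RPMI-8226 (adjusted p = 0.0262 for a line difference). No line difference in the CPI203 effect was called without the JJN3 control array, or with the JJN3 and RPMI-8226 arrays averaged. The largest falls were RIPOR2, which fell by 1.37 ± 0.29 (adjusted p = 0.0272), the nuclear receptor gene RXRA, which fell by 1.35 ± 0.29, NRROS, which fell by 1.35 ± 0.21 (adjusted p = 0.0153), and the necroptosis effector MLKL, which fell by 1.34 ± 0.26. CACNB2 (-1.20), SLC35G1 (-1.19), HPDL (-1.16), NFIC (-1.12), BEND3 (-1.12) and UBXN8 (-1.11) followed.

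Ikaros, Aiolos and MYC transcripts fell in this comparison. IKZF1 fell by 1.04 ± 0.19 (2.05-fold lower, adjusted p = 0.0191), with -0.31 in ARP1, -1.46 in JJN3 and -1.34 in RPMI-8226. IKZF3 fell by 0.83 ± 0.14 (adjusted p = 0.018) in 3 of 3 lines, and MYC fell by 0.51 ± 0.10 (1.42-fold lower, adjusted p = 0.025), with -0.33, -0.33 and -0.86. HEXIM1 rose by 1.14 ± 0.22 (adjusted p = 0.022), SERPINI1, another transcript used to follow BET inhibition, by 1.38 ± 0.28 (adjusted p = 0.0245), and the survival gene MCL1 by 0.43 ± 0.10 (adjusted p = 0.0347), each in 3 of 3 lines. These rises were smallest in ARP1. In ARP1, JJN3 and RPMI-8226 they were 0.23, 1.42 and 1.78 for HEXIM1, 0.27, 1.85 and 2.03 for SERPINI1, and 0.14, 0.56 and 0.60 for MCL1. IRF4, the plasma cell survival factor, stood at 0.37 ± 0.12 (adjusted p = 0.0924), CRBN at 0.27 ± 0.15 (adjusted p = 0.308), CCR2 at -0.03 ± 0.12 (adjusted p = 0.933) and BCL2L11 at 0.28 ± 0.19 (adjusted p = 0.437). CDKN1A was at -1.1 in ARP1 against 0.78 and 0.99 in JJN3 and RPMI-8226 (mean 0.22, adjusted p = 0.795). In limma 1105 genes passed, 500 higher and 605 lower, of which 490 and 603 moved the same way in all 3 lines and 36 and 24 moved at least 2-fold. The count was 0 without JJN3, 0 without RPMI-8226, 2399 without ARP1 (1228 higher and 1171 lower), 118 without the JJN3 control array, 0 with the JJN3 and RPMI-8226 arrays averaged and 0 with no line block. A variance trend and robust fit called 1686 genes, and 1775 probe sets passed when tested singly.

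Of the 19 histone genes measured, 12 rose with CPI203 on average and none fell, or 15 when adjusted over the list alone (median 0.94). H2BC5 rose by 1.22 ± 0.11 (adjusted p = 0.00371) and H2BC4 by 0.94 ± 0.11 (adjusted p = 0.00873); the list test gave camera adjusted p = 1.14e-14, and adjusted p = 0.0778 with an estimated correlation. Of the 12 BET-induced genes, which share 5 members with the histone list, 8 rose and none fell, against 10 and 1 when adjusted over the list alone. H2BC11 rose by 1.33 ± 0.16 and the polyamine acetyltransferase gene SAT1 by 0.95 ± 0.17 (list median 0.97, camera adjusted p = 3.75e-08, adjusted p = 0.136 with an estimated correlation). Of 55 MYC targets 18 fell and none rose, against 34 and 1 when adjusted over the list alone. POLR1B, an RNA polymerase I subunit, fell by 0.66 ± 0.08, and the ribosome biogenesis genes BYSL, NOP16 and PPAN fell by 0.61 ± 0.10, 0.59 ± 0.09 and 0.56 ± 0.09 (list median -0.27, camera adjusted p = 1.14e-14, adjusted p = 0.171 with an estimated correlation). Without the JJN3 control array, which carried the immunoglobulin transcripts, 6 histone genes and 3 BET-induced genes rose and 2 MYC targets fell, with list medians of 0.87, 1.05 and -0.27. None of these lists had a called gene without JJN3, without RPMI-8226 or with those arrays averaged, and with the averaged arrays the medians were 0.80, 0.85 and -0.24.

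Immediate early genes also rose with CPI203, 7 of 17 against 1 that fell (8 and 1 when adjusted over the list alone). EGR1 rose by 0.87 ± 0.13, FOS by 1.04 ± 0.19 and ZFP36 by 1.23 ± 0.23, and the member that fell was MYC (median 0.47, camera adjusted p = 4.84e-05, adjusted p = 0.193 with an estimated correlation). Of 20 unfolded protein response genes 5 rose and none fell, against 9 and 2 when adjusted over the list alone. They included HERPUD1, a factor of ER-associated degradation, at 0.60 ± 0.09, PPP1R15A at 0.86 ± 0.17 and ATF3, a stress factor that is also on the immediate early list, at 1.22 ± 0.25 (camera adjusted p = 0.000381, adjusted p = 0.195 with an estimated correlation). Of 14 P-TEFb and BET protein genes, which share HEXIM1 with the BET-induced list, 4 rose and 1 fell, against 6 and 1 when adjusted over the list alone. BRD2 rose by 0.61 ± 0.12 and CDK9 by 0.37 ± 0.08, while HEXIM2 fell by 0.68 ± 0.14 (camera adjusted p = 0.00286, adjusted p = 0.184 with an estimated correlation). Among 13 cereblon ligase and neosubstrate genes 4 fell and none rose, or 7 when adjusted over the list alone. Beside IKZF1 and IKZF3 these members were ZNF692, which fell by 0.97 ± 0.19, and CUL4A, which fell by 0.29 ± 0.08 (camera adjusted p = 0.00465, adjusted p = 0.136 with an estimated correlation). The anti-apoptotic gene BCL2L1 fell by 0.70 ± 0.12 (adjusted p = 0.0183). Without the JJN3 control array 1 immediate early and 1 unfolded protein response gene rose, and no gene of the P-TEFb or cereblon lists passed. The medians of these 4 lists went from 0.47 to 0.38, 0.21 to 0.20, 0.25 to 0.25 and -0.24 to -0.22. None of these 4 lists had a called gene without JJN3, without RPMI-8226 or with those arrays averaged.

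LenDex was compared with control for the effect of lenalidomide plus dexamethasone. Glucocorticoid receptor targets were prominent among the rises. TSC22D3 (GILZ), a mediator of glucocorticoid action, rose 11.4-fold (3.51 ± 0.34, adjusted p = 0.00661), the chemokine receptor gene CXCR4 5.38-fold (2.43 ± 0.20, adjusted p = 0.00258) and the receptor co-chaperone FKBP5 3.51-fold (1.81 ± 0.12, adjusted p = 0.00089), each in 3 of 3 lines. FAR2 (2.16), CYSLTR1 (2.06), TSPYL2 (1.58), ARHGEF3 (1.56), ZNF189 (1.41), LRRC1 (1.4) and PNPLA8 (1.32) also rose. HMOX1, the heme oxygenase gene, fell by 1.60 ± 0.20 (adjusted p = 0.0214) and the RNA polymerase III subunit gene POLR3G fell by 1.30 ± 0.18 (adjusted p = 0.0283). FJX1 (-1.11), PARM1 (-0.99), GEMIN5 (-0.95), PDCD2L (-0.94), EAF2 (-0.86), ZNF764 (-0.83), PPP1R9B (-0.82) and the mitochondrial methionyl-tRNA synthetase gene MARS2 (-0.79) fell as well, in all 3 lines. MYC stood at -0.37 ± 0.15 (adjusted p = 0.287), IKZF1 at -0.32 ± 0.26 (adjusted p = 0.673) and IKZF3 at -0.12 ± 0.20 (adjusted p = 0.851). Of 34 glucocorticoid-induced genes 3 rose, or 7 when adjusted over the list alone (camera adjusted p = 5.28e-08, adjusted p = 0.223 with an estimated correlation), and of 55 MYC targets 3 fell, or 29 when adjusted over the list alone (camera adjusted p = 9.62e-18, adjusted p = 0.223 with an estimated correlation). In limma 70 genes passed, 37 higher and 33 lower (52.9% higher, against 73.5% of 49 after cyclic loess, 40.1% of 137 with a stricter level filter and 35.9% of 287 with a variance trend and robust fit). The count was 298 without ARP1, 0 without JJN3, 2 without RPMI-8226, 2 without the JJN3 control array, 2 with the JJN3 and RPMI-8226 arrays averaged, 1 with no line block and 0 in a fit of these 6 arrays alone.

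Over both CPI203 backgrounds, the same glucocorticoid targets were among the largest rises in the average effect of LenDex. TSC22D3 rose 11.9-fold (3.58 ± 0.24, adjusted p = 0.000224), CXCR4 5.75-fold (2.52 ± 0.14, adjusted p = 6.9e-05) and FKBP5 3.65-fold (1.87 ± 0.09, adjusted p = 2.47e-05), in 3 of 3 lines each. The glucuronosyltransferase genes UGT2B15, UGT2B7 and UGT2B17 rose by 2.08 ± 0.35, 1.98 ± 0.38 and 1.86 ± 0.42, and the aldo-keto reductase gene AKR1C2 by 1.79 ± 0.40. In ARP1, JJN3 and RPMI-8226 the changes were 0.74, 3.16 and 2.35 for UGT2B15 (adjusted p = 0.0152 for a line difference) and 0.16, 2.09 and 3.12 for AKR1C2 (adjusted p = 0.0121). The members of each of these families have near-identical sequences, and signal shared between their probe sets was not excluded. FAR2 rose by 2.02, SLITRK6 by 1.92 and TIPARP by 1.84. GPR183, a receptor that guides B cells, fell by 1.63 ± 0.37 (adjusted p = 0.0408), P2RY10 fell by 1.62 ± 0.27 (adjusted p = 0.0146), HMOX1 fell by 1.45 ± 0.14 (adjusted p = 0.00213) and the myeloma surface antigen gene SLAMF7 fell by 1.32 ± 0.22 (adjusted p = 0.0146), the last 3 in 3 of 3 lines. IL15RA (-1.16), PHLDA1 (-1.12), ACKR3 (-1.07), PLD6 (-1.04), POLR3G (-0.97) and GEMIN5 (-0.94) also fell. GPR183 was at -0.07 in ARP1, -2.61 in JJN3 and -2.21 in RPMI-8226 (adjusted p = 0.0121 for a line difference), and PHLDA1 at -0.10, -1.53 and -1.72 (adjusted p = 0.0456). Without the JJN3 control array no line difference in the LenDex effect was called. MYC was at -0.31 ± 0.10 (adjusted p = 0.136), lower in all 3 lines, and PER1 at 1.15 ± 0.33 (adjusted p = 0.0823), higher in all 3. NR3C1, the glucocorticoid receptor gene, was at -0.25 ± 0.08 (adjusted p = 0.108). In limma 645 genes passed, 262 higher and 383 lower (40.6% higher, against 58.9% of 644 after cyclic loess and 56.1% of 918 without ARP1). The count was 2 without JJN3, 5 without RPMI-8226, 237 without the JJN3 control array, 4 with the JJN3 and RPMI-8226 arrays averaged and 1 with no line block. It was 1008 with a stricter level filter and 1029 with a variance trend and robust fit, and 1235 probe sets passed when tested singly. The RPMI-8226 arrays with LenDex also differed from those without it in signs of RNA quality. Their 3' to 5' difference of actin was 0.448 (LenDex) and 0.391 (Combo) against 0.274 (control) and 0.226 (CPI203), that of GAPDH -0.087 and -0.102 against -0.216 and -0.152, and their ribosomal RNA probe sets were at 12.41 and 12.546 against 12.144 and 12.205.

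Of 34 glucocorticoid-induced genes 7 rose and none fell with LenDex on average, against 15 and 1 when adjusted over the list alone. DDIT4, an mTOR inhibitor, rose by 1.54 ± 0.24 (list median 0.37, camera adjusted p = 2.34e-08, adjusted p = 0.235 with an estimated correlation). Of 55 MYC targets 16 fell and none rose, or 33 when adjusted over the list alone. PPAN fell by 0.68 ± 0.09, POLR1B fell by 0.62 ± 0.08 and WDR74 fell by 0.51 ± 0.07 (list median -0.27, camera adjusted p = 1.26e-18, adjusted p = 0.211 with an estimated correlation). Cholesterol synthesis genes fell, 4 of 15 with none rising, or 8 when adjusted over the list alone. MSMO1 fell by 0.52 ± 0.08, CYP51A1 fell by 0.42 ± 0.09 and SQLE fell by 0.40 ± 0.09 (median -0.39, camera adjusted p = 1.6e-07, adjusted p = 0.211 with an estimated correlation). The mitotic kinase gene AURKA fell by 0.45 ± 0.09 and the cyclin gene CCNB1 fell by 0.43 ± 0.10, the 2 of 25 G2/M genes that passed, or 4 when adjusted over the list alone (camera adjusted p = 0.00405, adjusted p = 0.867 with an estimated correlation). Of 15 BCL2 family genes 3 rose, or 4 when adjusted over the list alone, and none fell. These were the pro-apoptotic genes BBC3 at 0.77 ± 0.11, BAK1 at 0.42 ± 0.10 and BIK at 0.34 ± 0.08 (camera adjusted p = 0.732). Of the 22 NF-kB targets CFLAR rose by 1.19 ± 0.20, NFKB2 fell by 0.45 ± 0.08 and RELB fell by 0.60 ± 0.12, with 2 rising and 6 falling when adjusted over the list alone (camera adjusted p = 0.0608). None of 19 histone genes passed. Of 36 interferon-stimulated genes 3 rose, or 4 when adjusted over the list alone, and none fell; the list median was -0.03 while the test ran upward (camera adjusted p = 0.856). Without the JJN3 control array 5 glucocorticoid-induced, 1 BCL2 family and 1 interferon-stimulated gene rose, 7 MYC targets and 4 cholesterol synthesis genes fell, no G2/M gene passed and 1 NF-kB target passed in each direction. The medians of the glucocorticoid, MYC and cholesterol lists were then 0.38, -0.28 and -0.39, and without RPMI-8226 or without JJN3 no gene of the MYC or cholesterol lists passed.

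**Figure D2:**
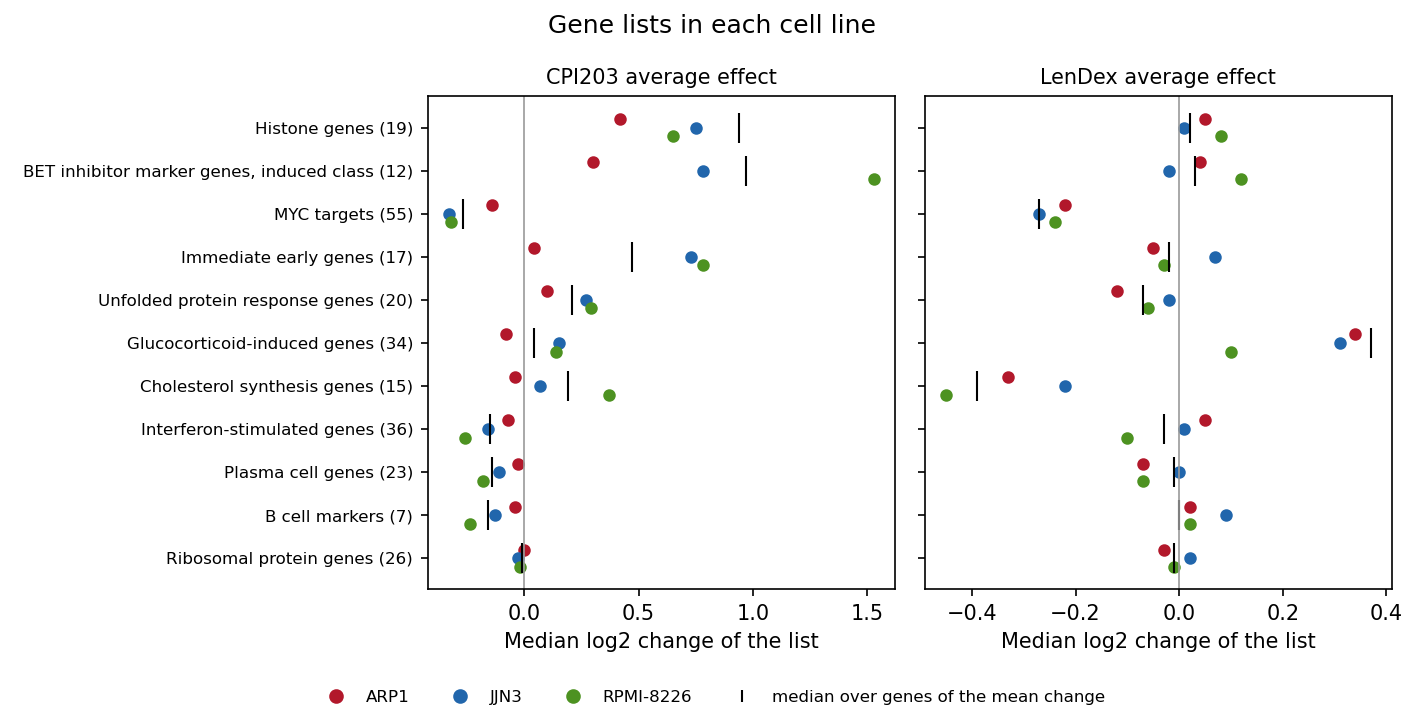
Median log2 change (horizontal axis) of 11 gene lists under CPI203 (left) and LenDex (right), each averaged over the other treatment, with the number of measured genes in brackets. Points are medians within each labelled cell line and vertical ticks the median over genes of the mean of the 3 lines; histone genes (0.94) and BET-induced genes (0.97) were higher under CPI203, glucocorticoid-induced genes (0.37) under LenDex, and MYC targets were lower under both (-0.27 each).

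Combo was compared with control for the effect of all 3 drugs together. TSC22D3 rose 14.3-fold (3.84 ± 0.34, adjusted p = 0.00249), TIPARP 6.43-fold (2.69 ± 0.60, adjusted p = 0.0249), SERTAD1 6.04-fold (2.60 ± 0.58, adjusted p = 0.0247) and CXCR4 5.24-fold (2.39 ± 0.20, adjusted p = 0.00249), each in 3 of 3 lines. UGT2B7 rose 4.21-fold, KLHL24 4.01-fold, MT1X 3.99-fold, DDIT4 3.84-fold, FKBP5 3.66-fold and the growth factor receptor gene FGFR1 3.58-fold. P2RY10 fell by 2.24 ± 0.38 (adjusted p = 0.011), IL15RA, which encodes a chain of the interleukin-15 receptor, fell by 1.99 ± 0.33 (adjusted p = 0.01), PLD6 fell by 1.92 ± 0.23 (adjusted p = 0.00351) and the adhesion gene VCAM1 fell by 1.92 ± 0.48 (adjusted p = 0.0386). HPDL (-1.87), SLC35G1 (-1.85), SLAMF7 (-1.85), BEND3 (-1.80), TASL (-1.74) and CACNB2 (-1.66) fell as well, in all 3 lines. MYC fell by 0.81 ± 0.15 (1.76-fold lower, adjusted p = 0.0128), with -0.71, -0.65 and -1.08 in ARP1, JJN3 and RPMI-8226. IKZF1 fell by 1.22 ± 0.26 (adjusted p = 0.0222) and IKZF3 fell by 1.08 ± 0.20 (adjusted p = 0.0135), in 3 of 3 lines. SERPINI1 rose by 1.63 ± 0.40 (adjusted p = 0.0342), H2BC21 by 1.37 ± 0.24 (adjusted p = 0.0112) and PER1 by 1.76 ± 0.46 (adjusted p = 0.0437). PER1 hardly moved in ARP1, with log2 levels of 5.64 in control and 5.67 under Combo. It went from 5.44 to 8.56 in JJN3 and from 5.55 to 7.68 in RPMI-8226. SERPINI1 went from 7.10 to 7.41 in ARP1, from 6.39 to 8.78 in JJN3 and from 6.59 to 8.78 in RPMI-8226. HEXIM1 (1.06 ± 0.31, adjusted p = 0.0637), MCL1 (0.48 ± 0.14, adjusted p = 0.0652) and IRF4 (0.29 ± 0.17, adjusted p = 0.344) did not pass. In limma 1388 genes passed, 539 higher and 849 lower (38.8% higher), of which 537 and 848 moved the same way in all 3 lines and 114 in each direction moved at least 2-fold. The count was 0 without JJN3, 2 without RPMI-8226, 2219 without ARP1, 300 without the JJN3 control array, 3 with the JJN3 and RPMI-8226 arrays averaged, 3 with no line block and 2 in a fit of these 6 arrays alone. When tested singly, 2473 probe sets passed. The balance of directions also moved, to 666 higher and 721 lower (48% higher) after cyclic loess and to 1191 higher and 1028 lower without ARP1.

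**Figure D3:**
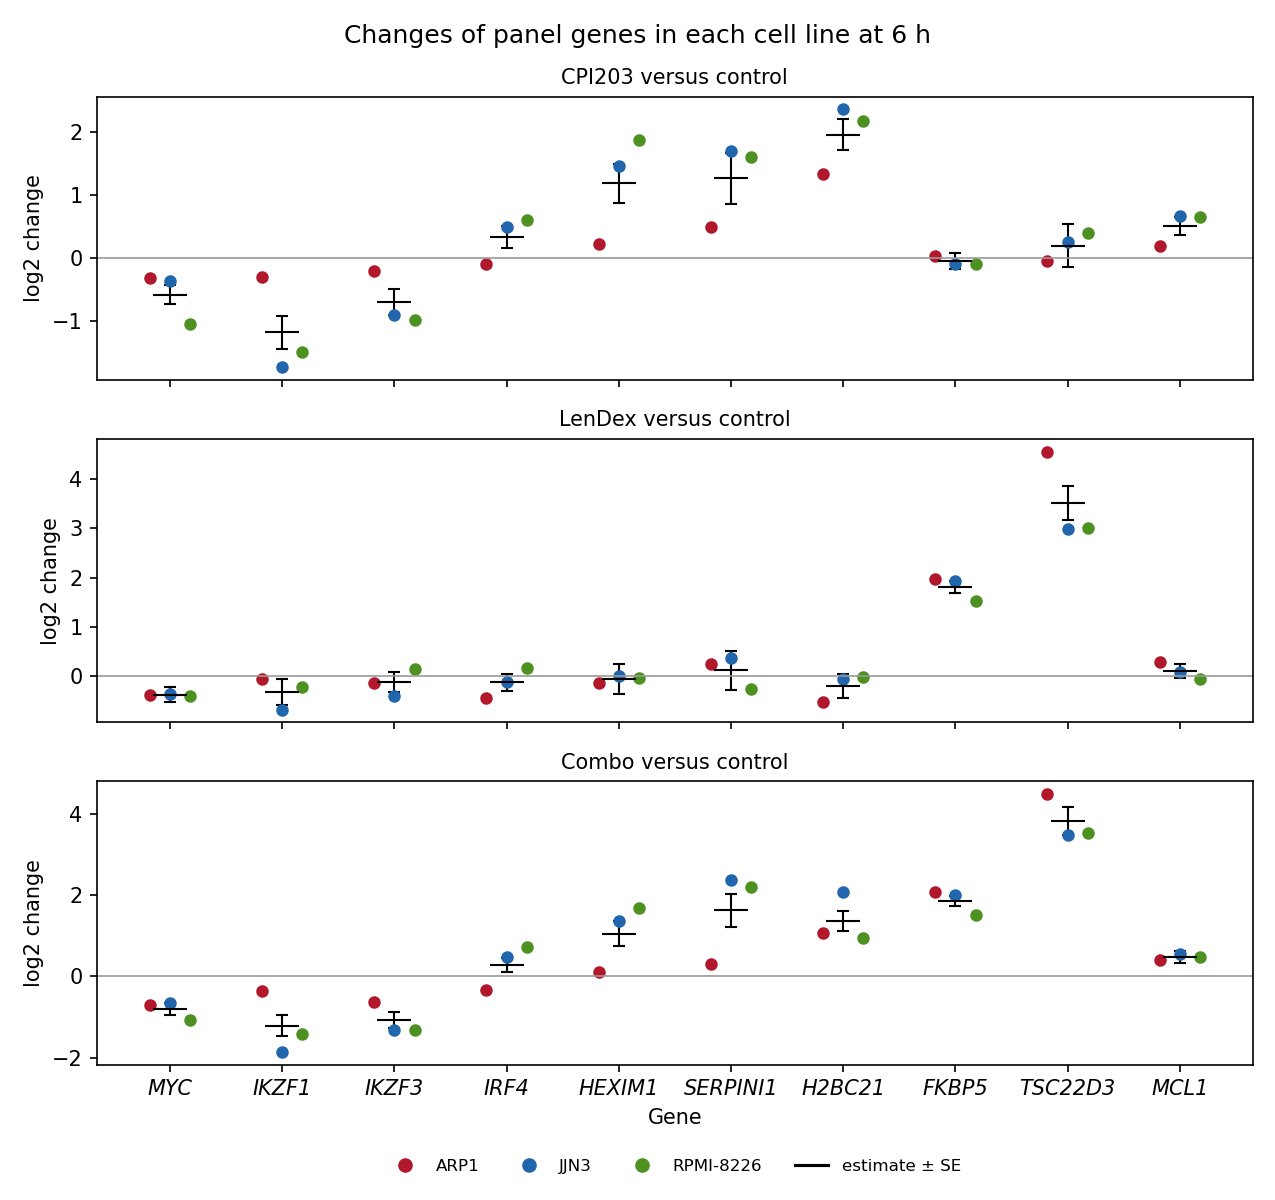
Log2 change from control (vertical axis) of 10 genes (horizontal axis) under CPI203, LenDex and Combo at 6 h; points are the 3 labelled cell lines, 1 array per line and group, and black bars the estimate ± SE. MYC was lower in all 3 lines under each treatment, and IKZF1 under Combo was at -0.37 in ARP1, -1.86 in JJN3 and -1.41 in RPMI-8226.

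MYC targets made up the largest called group under Combo, with 32 of 55 lower and none higher, or 42 when adjusted over the list alone. POLR1B fell by 1.28 ± 0.11, PPAN fell by 1.24 ± 0.13, NOP16 fell by 1.21 ± 0.13 and BYSL fell by 1.19 ± 0.14, in 3 of 3 lines each (list median -0.52, camera adjusted p = 4.98e-24, adjusted p = 0.12 with an estimated correlation). Of 19 histone genes 9 rose, or 15 when adjusted over the list alone, with H3C4 at 1.79 ± 0.18 and H2BC5 at 1.51 ± 0.15 (camera adjusted p = 1.45e-09, adjusted p = 0.12 with an estimated correlation). Of 34 glucocorticoid-induced genes 10 rose, or 16 when adjusted over the list alone, among them the thioredoxin inhibitor TXNIP at 1.61 ± 0.22 (median 0.66, camera adjusted p = 3.38e-07, adjusted p = 0.196 with an estimated correlation). TXNIP is also 1 of the 5 BET-induced genes, of 12, that rose, or 9 when adjusted over the list alone (camera adjusted p = 4.75e-06, adjusted p = 0.196 with an estimated correlation). Of 18 p53 targets 6 rose and 1 fell, against 8 and 2 when adjusted over the list alone. SESN2 rose by 0.75 ± 0.11, BBC3 by 1.02 ± 0.15 and TP53INP1 by 0.74 ± 0.13, while the death receptor gene FAS fell by 0.83 ± 0.13 (camera adjusted p = 0.00771, adjusted p = 0.267 with an estimated correlation). Of the cereblon list 3 genes of 13 fell, or 5 when adjusted over the list alone: IKZF1, IKZF3 and ZFP91, which fell by 0.55 ± 0.12 (camera adjusted p = 0.0169, adjusted p = 0.196 with an estimated correlation). BCL2L1 fell by 1.0 ± 0.17 (adjusted p = 0.011). Without the JJN3 control array 12 MYC targets fell and 3 histone, 7 glucocorticoid-induced and 3 BET-induced genes rose, 3 p53 targets rose and 2 fell, and no gene of the cereblon list passed. The medians of these 6 lists were then -0.51, 0.91, 0.63, 1.06, 0.19 and -0.30, against -0.52, 0.85, 0.66, 1.04, 0.35 and -0.21 with it. Without JJN3 no gene of these lists passed, and without RPMI-8226 the 2 that did were glucocorticoid-induced genes.

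What LenDex added to CPI203 was read from Combo against CPI203. The glucocorticoid targets TSC22D3, CXCR4 and FKBP5 rose by 3.65 ± 0.34 (adjusted p = 0.00437), 2.62 ± 0.20 (adjusted p = 0.00127) and 1.92 ± 0.12 (adjusted p = 0.00051), and the mRNA decay factor gene ZFP36L2 rose by 1.44 ± 0.14 (adjusted p = 0.00437), each in 3 of 3 lines. YRDC, a tRNA-modifying enzyme gene, fell by 0.86 ± 0.11 (adjusted p = 0.0406), MARS2 fell by 0.78 ± 0.10 (adjusted p = 0.0415) and the small nucleolar RNP assembly gene ZNHIT6 fell by 0.72 ± 0.10 (adjusted p = 0.0473). MYC stood at -0.24 ± 0.15 (adjusted p = 0.61) and IKZF1 at -0.04 ± 0.26 (adjusted p = 0.978). These 7 genes were the ones that limma called, 57.1% of them higher, against 83.3% of 6 after cyclic loess and 36% of 86 with a variance trend and robust fit. The count was 103 without ARP1, 0 without JJN3, 2 without RPMI-8226, 4 without the JJN3 control array, 2 with the JJN3 and RPMI-8226 arrays averaged, 1 with no line block and 0 in a fit of these 6 arrays alone. It was 12 with a stricter level filter, and 40 probe sets when tested singly. Across genes, these changes correlated with those of LenDex against control, which use no shared array, with Pearson r = 0.645 and Spearman rho = 0.491. The called genes had 4 rises and 2 falls in common. Of 34 glucocorticoid-induced genes 3 rose, or 8 when adjusted over the list alone (camera adjusted p = 1.71e-07, adjusted p = 0.292 with an estimated correlation). None of 55 MYC targets passed over all genes and 10 fell when adjusted over the list alone (camera adjusted p = 3.1e-13, adjusted p = 0.292 with an estimated correlation), and for 15 cholesterol synthesis genes these counts were 0 and 8 (camera adjusted p = 1.71e-07, adjusted p = 0.292 with an estimated correlation).

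What CPI203 added to LenDex was read from Combo against LenDex. No gene passed in limma, with 2264 at an unadjusted p under 0.05. The histone genes H3C4 at 1.57 ± 0.18 and H2BC5 at 1.20 ± 0.15, and the genes FERMT1 at -1.15 ± 0.14 and FAM78A at -0.99 ± 0.13, came closest (adjusted p = 0.0569 each), with the same direction in 3 of 3 lines. MYC stood at -0.44 ± 0.15 (adjusted p = 0.232), IKZF1 at -0.90 ± 0.26 (adjusted p = 0.207) and IKZF3 at -0.95 ± 0.20 (adjusted p = 0.131). When adjusted over the list alone, 12 of 19 histone genes rose, where over all genes none did (camera adjusted p = 6.72e-12, adjusted p = 0.123 with an estimated correlation). Without ARP1 715 genes passed, with a stricter level filter 4, after cyclic loess 2, and with a variance trend and robust fit 61. Across genes, these changes correlated with those of CPI203 against control, from other arrays, with Pearson r = 0.688 and Spearman rho = 0.565.

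Whether the Combo departed from the sum of the separate log2 effects was tested as an interaction. No gene passed in limma, with 472 at an unadjusted p under 0.05. For MYC the departure was 0.14, with a 95% interval from -0.33 to 0.60, for IKZF1 0.28 (-0.55 to 1.1), for IKZF3 -0.25 (-0.87 to 0.37) and for IRF4 0.08 (-0.46 to 0.62). TSC22D3 had 0.14 (-0.93 to 1.20) and FKBP5 0.11 (-0.28 to 0.50). The smallest p-values in each direction belonged to HIVEP3 at 0.88 ± 0.17 and ZNF101 at -0.85 ± 0.14 (adjusted p = 1 each), with the same sign in 3 of 3 lines. Of the 55 MYC targets none passed, with a list median of 0.08 (camera adjusted p = 0.124). The interval lay within 1 log2 unit of 0 for 14075 of the 15173 genes, taken singly.

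A difference in response between the labelled lines was called for some genes. With CPI203, 49 genes passed the test of a line difference, and 2237 had an unadjusted p under 0.05. HEXIM1 moved by 0.23 in ARP1, 1.42 in JJN3 and 1.78 in RPMI-8226 (adjusted p = 0.0262), and the B cell maturation antigen gene TNFRSF17 by -0.20, -1.69 and -3.04 (adjusted p = 0.0262). With LenDex, 56 genes passed, and 2071 had an unadjusted p under 0.05. ZBTB16, a glucocorticoid-induced transcription factor gene, moved by 3.24, 0.30 and 0.07, the glutamine synthetase gene GLUL by 2.79, 0.54 and 0.62, and AKR1C2 by 0.16, 2.09 and 3.12 (adjusted p = 0.0121 each). Across genes, the CPI203 effects in JJN3 and RPMI-8226 correlated with Pearson r = 0.706, against 0.256 for ARP1 with JJN3 and 0.241 for ARP1 with RPMI-8226. The corresponding values for LenDex were 0.564, 0.218 and 0.297. Other pairings of the 6 differences of each drug, 15 with the real one and too few for a share under 0.05, gave at most 9 genes for CPI203 and 44 for LenDex. Without the JJN3 control array limma called 0 genes in either test, with 1800 for CPI203 and 1478 for LenDex at an unadjusted p under 0.05. The CPI203 count was 0 with the JJN3 and RPMI-8226 arrays averaged, 83 with a stricter level filter, 673 with a variance trend and robust fit and 13 when probe sets were tested singly; the last 2 settings gave 471 genes and 123 probe sets for LenDex, and with the arrays averaged 51 genes passed for LenDex, 46 of them among the 56.

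Markers of other cell types gave no called gene in any comparison of treatments over all 3 lines. Without ARP1 the B cell markers did: 3 of 7 fell with CPI203 on average, 1 under CPI203 alone and 2 under Combo, while 1 rose and 1 fell with LenDex, alone and on average. The lists held 8 T cell, 7 monocyte and macrophage, 6 fibroblast, 7 epithelial and 7 B cell genes, and under CPI203 on average their camera adjusted p ranged from 0.166 for B cell markers to 0.866 for fibroblast markers. None of 26 ribosomal protein genes changed in either average effect, with a list median of -0.01 in both (camera adjusted p = 0.768 for CPI203 and 0.856 for LenDex). Among the other lists, CPI203 on average gave 1 rise (IRF7 at 1.38) and 4 falls among 36 interferon-stimulated genes, or 1 and 6 when adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.304 with an estimated correlation). It gave 2 rises (IDI1 at 0.70 and INSIG1 at 0.63) among 15 cholesterol synthesis genes, the same number when adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.337 with an estimated correlation). Of 27 G1/S and DNA replication genes 2 rose, RRM2 at 0.45 among them, and 3 fell, with MCM2 at -0.46, against 2 and 5 when adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.509 with an estimated correlation). Of 18 p53 targets 3 rose, led by SESN2 at 0.59, and FAS fell by 0.39, against 4 and 1 when adjusted over the list alone (camera adjusted p = 0.00465, adjusted p = 0.195 with an estimated correlation). CDKN2D at 0.59 was the 1 riser of 6 cyclin-dependent kinase inhibitor genes (camera adjusted p = 0.0535) and CCNF at 0.48 that of 25 G2/M genes (camera adjusted p = 0.173). MYC was the 1 gene of 12 BET-repressed genes that fell (camera adjusted p = 0.0805). CCR2, another of the 12, was near background on all arrays, so a fall of it could not have been seen. Of 34 glucocorticoid-induced genes 3 rose with CPI203 (MT1X, GADD45B and TXNIP; camera adjusted p = 0.0721), of 22 NF-kB targets IER3 rose and NFKBIE fell (0.543), of 23 plasma cell genes HERPUD1 rose and CAV1 fell (0.182), and of 15 BCL2 family genes MCL1 rose and BCL2L1 fell (0.768). At most 1 gene of each of these other lists rose and none fell without the JJN3 control array, and none passed with the JJN3 and RPMI-8226 arrays averaged.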

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

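The tests of the explanations weighed here, the counts of other splits, and the genes MAF, IGKC and JCHAIN were chosen after the values were seen; the tests of a difference between lines were planned.

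A difference in response between the labelled lines was called for 49 genes with CPI203 and 56 with LenDex, in a test of the difference itself. Without the JJN3 control array both counts were 0. With the JJN3 and RPMI-8226 arrays averaged they were 0 and 51. For CPI203, LMO2, a hematopoietic transcription cofactor gene, changed by -0.41 in ARP1, -3.24 in JJN3 and -0.12 in RPMI-8226, and the erythroid factor gene KLF1 by -0.15, -2.54 and -0.01. NFE2 changed by 0.08, -1.85 and 0.24, OXTR by 0.18, -1.51 and -1.92, and the fetal globin gene HBG1 by -0.04, -0.09 and 1.64 (adjusted p = 0.0261 for each of these 5). IFIT2 changed by 0.39, -0.15 and 1.67, TNFSF9 by -0.21, 1.42 and 1.41, TNFRSF17 by -0.20, -1.69 and -3.04 and ADARB1 by 0.39, 2.14 and 0.32, and SERTAD1, HEXIM1, MT1X and H2AC8 had smaller rises in ARP1 (adjusted p = 0.0262 for each of these 8). DHRS2 (adjusted p = 0.0369), CSRNP2 (adjusted p = 0.0384), H2AC25 (adjusted p = 0.0459) and JUND (adjusted p = 0.0467) also had smaller rises in ARP1, with 0.41, 0.34, 0.13 and 0.46 there.

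LMO2, KLF1 and NFE2 were at log2 levels of 8.68, 8.34 and 6.92 on the JJN3 control array, 5.71, 5.75 and 5.45 on that of ARP1 and 4.81, 4.54 and 4.98 on that of RPMI-8226. Nonspecific control probe sets lay between 4.87 and 4.98, so a fall of these 3 genes could not have been seen on the RPMI-8226 arrays and only a small one on those of ARP1. HBG1, which rose in RPMI-8226 alone, was at 6.77 on its control array, against 12.40 on that of ARP1 and 13.30 on that of JJN3. Whether the high levels there limited a rise was not tested.

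For LenDex, larger changes in ARP1 were seen in CD160 (3.39, -0.16 and 0.01), ZBTB16 (3.24, 0.30 and 0.07), GLUL (2.79, 0.54 and 0.62), SNX30 (2.36, 0.15 and 0.09) and NUDT16 (2.24, 0.38 and 0.23). Changes nearly absent from ARP1 were seen in AKR1C2 (0.16, 2.09 and 3.12), AKR1C1 (-0.16, 1.67 and 3.25), TBC1D9 (-0.15, 1.97 and 1.61) and GPR183 (-0.07, -2.61 and -2.21), with adjusted p = 0.0121 for each of these 9 genes. WWC2 changed by -1.84, -0.05 and -0.15 (adjusted p = 0.0123), UGT2B15 by 0.74, 3.16 and 2.35 (adjusted p = 0.0152), TSC22D3 by 4.55, 3.11 and 3.08 (adjusted p = 0.0307) and PHLDA1 by -0.10, -1.53 and -1.72 (adjusted p = 0.0456). The larger rise of TSC22D3 in ARP1 began from a lower control level, 7.59 against 9.73 in JJN3 and 9.57 in RPMI-8226. With LenDex it reached 12.14 in ARP1, 12.71 in JJN3 and 12.57 in RPMI-8226. Of 2992 probe sets with several gene symbols or none, which the comparisons of genes leave out, 81 passed for the CPI203 average effect and 71 for that of LenDex.

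The arrays labelled JJN3 and RPMI-8226 carried B cell transcripts and little SDC1 or PRDM1. IRF4, TNFRSF13B and FCRL5, also on the plasma cell list, averaged higher there than on the ARP1 arrays. Array-wise normalization by the authors is argued against, since it keeps the order of genes within an array and at least 4 of 7 B cell markers ranked over 20 percentile points above their highest ARP1 rank on each of the 8 arrays. That count replaced a first test, the gap between the marker medians (lowest 56.6 on the 8 arrays, highest 39.6 on the ARP1 arrays), which fell short of the same 20 points and had decided nothing. A MAF-driven myeloma type shared by both labels is also argued against, with MAF at 6.47 at most on the 8 arrays and at 10.87 or more on the ARP1 arrays, whereas related cells under both labels would fit: 18 genes differed by over 3 log2 units on every array between these labels, against 287 and 329 for the comparisons with ARP1 (5.84% of their mean). A candidate explanation is therefore that the labels of both these lines do not name the cells measured, which no genotype was available to test. The likeness of these labels was not complete. On the JJN3 and RPMI-8226 arrays HBG1 averaged 13.27 and 7.66, HBZ 9.76 and 4.97, and the epithelial marker KRT18 9.20 and 5.57. The cause of these differences was not tested. A true likeness of correctly labelled lines is argued against for both labels. MAF is translocated in both named lines, yet it averaged 5.74 on the JJN3 and 4.79 on the RPMI-8226 arrays. Medians of the plasma cell genes were 7.57 to 8.33 and 7.55 to 8.65 there, against 10.75 to 11.07 on the ARP1 arrays.

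The JJN3 control array carried transcripts typical of the ARP1 arrays, with IGKC at 9.32 against 5.55 at most on the other JJN3 arrays and JCHAIN at 9.63 against 7.80 at most. A fall of these transcripts under treatment that ARP1 cells share is argued against: over 64 genes high on the ARP1 and low on the RPMI-8226 control array the median change was -0.04 in ARP1 (quartiles -0.19 and 0.14) and -0.24 in JJN3, and 7 of them that fell over 2-fold in JJN3 had a median of -0.08 in ARP1 (lowest -0.90). ARP1 RNA or cells in the JJN3 control sample cannot be told apart from other causes: of 50 genes high on all ARP1 and low on all RPMI-8226 arrays, 32 (64%) were highest on this array of the 4, where chance gives 25% and the other JJN3 arrays had at most 7. The level of these genes would need an ARP1 share with a median of 0.481% (quartiles 0.137 and 1.46). Of these genes, 25 lay at least 1 log2 unit under the level at the share that IGKC would need. That gap decides nothing, since the shares treat array values as proportional to RNA amounts and some of these genes lay near background. A response of immunoglobulin genes in the JJN3 cells alone stays open and was not tested.

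CPI203 effects were smaller in ARP1 than on the other arrays: 6 genes moved over 2-fold the same way in both of its pairs of arrays, against 126 in JJN3 and 217 in RPMI-8226. A failure of 1 ARP1 array is argued against, since over 140 genes chosen for changes in JJN3 and RPMI-8226 the slopes of the ARP1 effects were 0.16 and 0.15 in the 2 pairs, which share no array. Such a choice of genes can lower the slope in the line left out, but with JJN3 or RPMI-8226 left out it was 1.09 and 1.11, over 6 and 5 genes only. A uniformly smaller response cannot be told apart from one that differs between genes. The variance of ARP1 effects around the slope was 3.5 times the error variance of the mean of the 2 pairs, estimated from their difference. The same ratio was 2.65 for JJN3 and 1.08 for RPMI-8226 over those few genes, so the 3.5 has no firm yardstick. Pairs of single arrays also do not give the variation between lines. A biological difference between the lines, or the likeness of the arrays under the other labels, may account for it, and neither was tested.

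Other splits of the arrays were counted for each number of called genes. Chance can be excluded for the average effects only if the 6 pairs of arrays are taken as independent units: of 32 splits that part the arrays of each pair, 1, the real one, gave as many genes as the real 1105 for CPI203 (highest other 0), and likewise 1 of 32 for the 645 of LenDex (highest other 0). With the 3 lines as units there are 4 splits, too few for a share under 0.05, and 1 of the 4, the real one, gave as many (highest other 0 for both effects). With JJN3 and RPMI-8226 averaged the counts were 0 and 4. The splits were also too few in the other comparisons. With 10 splits, the real count and the highest other were 1 and 0 for CPI203 against control, 70 and 0 for LenDex against control, 1388 and 1 for Combo against control, 7 and 0 for Combo against CPI203, and 0 and 1 for Combo against LenDex. The interaction had 4 splits, with 0 and 0, and the line differences 15, with 49 and 9 for CPI203 and 56 and 44 for LenDex.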

How the results depend on the processing

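Leaving out the JJN3 control array and averaging the JJN3 and RPMI-8226 arrays were chosen after seeing the data; the other settings were planned. None of 100 calls of genes named by rule turned its direction under the settings run for it. Neither did any of 192 further calls of list members, or any called list with an estimated correlation or with fry. Level filters, a variance trend and robust fit, no block and a fit of the 2 groups alone leave the estimated change the same. An estimated correlation likewise changes only the variance of a list test. These settings could not have turned a direction. Nor could leaving out or averaging lines, for the genes picked as moving the same way in every line. Of the 100 calls all held without a level filter, 97 of 97 tested with a mean log2 level of 6 or more, 95 with probe sets tested singly, 92 after cyclic loess, 90 with a variance trend and robust fit, 97 without ARP1, 35 without the JJN3 control array, 9 without RPMI-8226, 9 with JJN3 and RPMI-8226 averaged, 4 with no replicate block and 2 without JJN3. A fit of the 2 groups alone kept 1 of 54, and the mean of all probe sets of a gene 19 of 21. Of the 192 calls, 54 held without the JJN3 control array, and 0 without JJN3, without RPMI-8226 or with these averaged. Of 51 lists called by camera none held with an estimated correlation, and fry called 28. Without a level filter every count stayed within 1.5 times the value given above.

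Leaving out 1 line at a time gave from 0 to 1015 genes for CPI203 against control, 0 to 298 for LenDex against control, 0 to 2219 for Combo against control, 0 to 103 for Combo against CPI203, 0 to 715 for Combo against LenDex, 0 to 2399 for the CPI203 average effect and 2 to 918 for that of LenDex. The highest of these was without ARP1 each time, and the interaction stayed at 0. Fewer samples lower the power in all 3, and the cause of the contrast between them was not tested. With no replicate block, where the differences between lines enter the error, the counts were 0 for CPI203, 1 for LenDex and 3 for Combo against control, 1 for Combo against CPI203, and 0 and 1 for the CPI203 and LenDex average effects; 564, 501, 1123, 383, 1061 and 801 genes had an unadjusted p under 0.05. A fit of the 2 groups alone, with fewer residual degrees of freedom, gave 0 for CPI203, 0 for LenDex and 2 for Combo against control, and 0 for Combo against CPI203. Without the JJN3 control array these 4 counts were 0, 2, 300 and 4, with 118 for the CPI203 average effect, 237 for that of LenDex and 0 for either line difference. With JJN3 and RPMI-8226 averaged they were 0, 2, 3 and 2, with 0 and 4 for the average effects and 0 and 51 for the line differences in the CPI203 and LenDex effects; fewer samples enter these fits.

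The cause was not tested for the following values. With a mean log2 level of 6 or more, LenDex against control gave 137 genes, Combo against CPI203 12, Combo against LenDex 4, the LenDex average effect 1008 and the line difference in the CPI203 effect 83. With all probe sets tested singly, which counts a gene more than once, CPI203 and Combo against control gave 7 and 2473, Combo against CPI203 40, the average effects 1775 for CPI203 and 1235 for LenDex, and the line differences 13 and 123. Cyclic loess gave 4 genes for CPI203 against control and 2 for Combo against LenDex. It moved the share of higher genes from 40.6% to 58.9% for the LenDex average effect, from 52.9% to 73.5% for LenDex against control from 57.1% to 83.3% for Combo against CPI203 and from 38.8% to 48% for Combo against control, where 1191 genes were higher and 1028 lower without ARP1. Without ARP1 the share was 56.1% for the LenDex average effect and 51.2% for that of CPI203, against 45.2% with it. For LenDex against control it was 40.1% with the stricter level filter and 35.9% with a variance trend and robust fit, which gave 36% for Combo against CPI203. A variance trend and robust fit gave 317 for CPI203 and 287 for LenDex against control, 86 for Combo against CPI203, 61 for Combo against LenDex, 1686 and 1029 for the CPI203 and LenDex average effects, and 673 and 471 for the line differences. The line differences were not run with a line left out, with no block or with 2 groups. Nonspecific control probe sets lay between 4.87 and 4.98 on each array, so a gene near a log2 level of 5 was at background.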

Other observations

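The overlap of the average effects was computed after the data were seen and carries no test. Among genes that fell with CPI203 on average (605) and with LenDex on average (383), 83 were the same, where 15.3 would be shared if the lists were independent, and 7 of the 83 were MYC targets. The overlap was 8 of 76 and 152 genes without the JJN3 control array (0.8 if independent), with 2 MYC targets. Both effects come from the same arrays with 1 residual variance per gene, so the lists are not independent even where no response is shared. Of the genes that rose with both, 15 were shared, against 8.6 if independent, and for opposite directions the numbers were 9 against 12.6 and 15 against 10.4. Across all genes the effects correlated with Pearson r = 0.112; genes are not independent replicates.

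Erythroid transcripts, chosen after their values were seen, differed between labelled lines. HBG1 was at 12.40 on the ARP1 control array, 13.30 on that of JJN3 and 6.77 on that of RPMI-8226, and the embryonic globin gene HBZ at 9.80, 9.94 and 5.02. LMO2 on the JJN3 arrays was at 8.68 in control and 8.53 with LenDex, against 5.36 with CPI203 and 5.38 with Combo. KLF1 was at 8.34 and 8.32, against 5.99 and 5.61. On the ARP1 and RPMI-8226 control arrays LMO2 was at 5.71 and 4.81 and KLF1 at 5.75 and 4.54, near the nonspecific control probe sets.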
